A study of Mus musculus with 9 samples.

How the data were processed

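RNA was measured by bulk sequencing of mouse (Mus musculus) jejunum. Per the labels' protocols, mice received sham treatment, TPN or starvation for 24 h, and a 5 cm piece of jejunum was harvested and opened lengthwise, so each library can hold every cell type of the piece. TPN stands for total parenteral nutrition, in textbook use the infusion of nutrients into a vein. Per the labels' protocols, mRNA was selected with oligo(dT) beads, fragmented and copied with random hexamers, with dNTPs in the second strand. That text names no step that marks the strand, so a gene and a gene overlapping it on the other strand may not be separable.

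The deposited table holds raw counts per gene symbol, made by the authors before deposit. The submitters' processing notes name FastQC 0.11.8, cutadapt 2.9, STAR 2.7.2e, featureCounts 2.0.0 and DESeq2 1.32.0, with the builds GRCm38 and mm10. The annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here. The counts are whole numbers that sum to different totals per library. The table has 21868 genes, of which 21689 match a gene name and 21676 a protein-coding gene of GENCODE release M21 on GRCm38, and that release gave the positions printed here. A further 9 columns of counts matched no sample in the labels and were used in no step.

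Groups and replicate numbers came from the labels, 3 libraries per group in 3 groups, all labelled as biological replicates. Total counts ran from 7779877 (TPN replicate 2) to 12084278 (sham replicate 3), so that 1 read was worth 0.0828 to 0.129 CPM (counts scaled to library size). Reads without molecular identifiers are not independent molecules, so counting intervals, given at 95%, cover counting error only. No pair of libraries of a group agreed within sampling noise: the chi-square per gene ran from 8.02 to 125.

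Differential expression was computed from the deposited counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 14668 and removed 7200, of which 3740 had no count in the 9 libraries. TMM factors scaled the libraries, a quasi-likelihood model with a mean per group was fitted to all 9 libraries with 6 residual degrees of freedom, and each comparison was a contrast. The Benjamini-Hochberg adjusted p had to be under 0.05 over the genes tested. The standard error given with a log2 fold change is its size divided by the square root of the F value. The biological coefficient of variation was 0.314 (common dispersion 0.0987). CPM values are TMM scaled and given as mean ± SD over 3 libraries.

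Before the data were examined, 45 gene lists (950 genes) were fixed, covering epithelial lineages, other cell types, absorption, lipid and energy metabolism, nutrient sensing, hormone responses, stress and immunity. Lists with at least 5 tested genes were tested with camera of limma 3.58.1 on voom weights at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 135 tests, again with an estimated correlation, and with fry, which asks whether a list's own genes move one way. List members were also counted with p adjusted over the list alone. The rule for named genes was fixed at the same time. It took, per comparison, the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, a mean log2 CPM of at least 3 and no overlap between groups, the 4 members with the smallest adjusted p in the direction of each list that passed camera, and a fixed set of sentinel genes. Genes outside the rule are marked where they appear, and some genes the rule took are not reported here.

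Alternatives were DESeq2 1.42.0, limma voom, other scaling factors or none, no filter or a stricter filter (CPM of at least 1 in at least 3 libraries), fits of only the groups compared, the replicate number as a block, a smooth muscle covariate, adjusted p under 0.01, a 2-fold minimum, and each library left out in turn. A fit without sham replicate 2 and starvation replicate 3 was added after seeing that they stood apart. Both comparisons against sham use the same 3 sham libraries, so chance overlap was estimated from 20 simulations of unchanged groups.

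With the real libraries' groups mixed, camera called 9 to 22 lists. In simulated counts it called 2 false lists in starvation against sham and 0 elsewhere. In TPN against sham, edgeR recovered 21 of 100 genes changed 2-fold and 76 of 100 changed 4-fold, with 4 false calls among 14429 genes, so an absent call at 2-fold carries little weight. DESeq2 recovered 44 and 92 with 31 false calls among 14668 genes.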

Results

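The data are 9 jejunal libraries, 3 each from sham, TPN and starved mice. Per library, 16023 to 16656 genes had at least 1 read. Apoa4, an apolipoprotein of chylomicrons, took 1.49% to 5.15% of the counts. The labels call the replicates biological but do not say that each came from a separate mouse. Where they did not, p-values measure only the spread between these samples, which may be technical.

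Markers of tissue layers set sham replicate 2 and starvation replicate 3 apart from the rest of their groups. Smooth muscle markers averaged 9.16 log2 CPM in sham replicate 2, against 6.14 and 6.30 in the other sham libraries and 4.74 to 6.34 in the remaining 6. Starvation replicate 3 had the highest villus tip markers, at 10.2 log2 CPM against 8.04 and 8.63 in the other starvation libraries. Its stem cell markers were the lowest of the 9 libraries, at 3.50 against 5.08 and 4.78. Pancreatic acinar markers averaged 4.29 to 9.57 log2 CPM in sham replicate 1, TPN replicates 1 and 2 and starvation replicate 1, and below 0 in the other 5 libraries. B and plasma cell markers were at 5.22 and 4.91 in starvation replicates 1 and 2 and at 0.78 in starvation replicate 3.

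**Figure D1:**
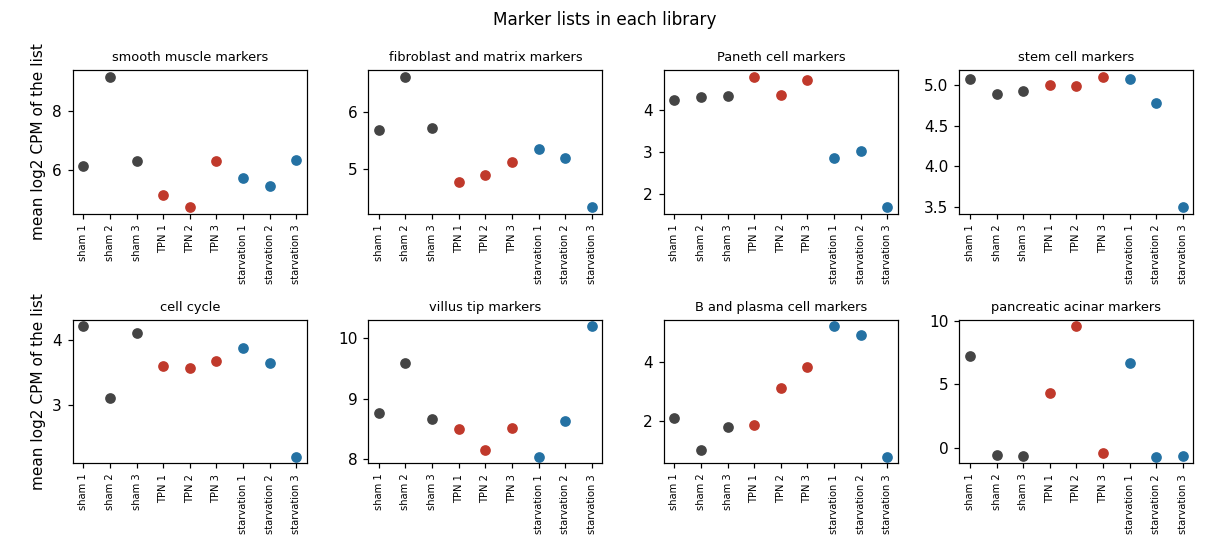
Mean log2 CPM of 8 marker lists (y axis, not starting at 0) in each of the 9 libraries (x axis, 1 point per library, coloured by group). Sham replicate 2 stands highest for smooth muscle markers at 9.16, starvation replicate 3 lowest for stem cell markers at 3.50, and the 3 starvation libraries lowest for Paneth cell markers, at 1.70 to 3.03.

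TPN was compared with sham to ask what changes when nutrients reach the jejunum only from the blood. By camera, the glucocorticoid response list rose in TPN, and lists of detoxification, sugar and peptide uptake and interferon response fell. The sugar and peptide lists did not pass fry, and no list passed with an estimated correlation. Fkbp5, a glucocorticoid-induced chaperone of the steroid receptor, rose from 15.5 ± 3.56 CPM in sham to 414 ± 22.4 in TPN (mean ± SD, n = 3). Its log2 fold change was 4.74 ± 0.24 (± SE). Cyp1a1, a detoxifying enzyme induced by the aryl hydrocarbon receptor, fell from 301 ± 26.2 to 0.176 ± 0.134 CPM, which is 9578 reads over the sham libraries and 6 over the TPN libraries. Over all 14668 genes 510 rose and 751 fell by the edgeR quasi-likelihood test, 282 and 380 of them at least 2-fold. All 1261 had groups that did not overlap, against 42.7% of all genes and a chance share of 10%.

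The glucocorticoid response list rose in TPN, with 9 higher and 0 lower of 16 tested members, and 12 and 0 adjusted over the list alone. Glucocorticoid response genes averaged a log2 fold change of 1.98 (camera adjusted p = 9.5e-11, or 0.220 with an estimated correlation; fry adjusted p = 0.00196). Large rises were in Zbtb16, a transcription factor (5.11 ± 0.42, quasi-likelihood adjusted p = 4.6e-04), and the metallothioneins Mt2 (4.64 ± 0.43) and Mt1 (3.10 ± 0.38). Ddit4, an inhibitor of mTORC1, rose by 2.31 ± 0.21. Among genes of fasting metabolism, Angptl4, an inhibitor of lipoprotein lipase, rose by 3.50 ± 0.30 and Pdk4, which restrains pyruvate oxidation, by 2.71 ± 0.33. The acute phase genes Serpina3n (4.47 ± 0.63) and Lrg1 (2.84 ± 0.71) and the predicted gene Gm45871 (2.83 ± 0.23) rose too. Cpt1a, the carnitine transferase of mitochondrial fatty acid entry, did not pass, with Cpt1a at 0.12 ± 0.32 (quasi-likelihood adjusted p = 0.832).

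The xenobiotic metabolism list fell, with 1 higher and 14 lower of 32 tested members, and 1 and 18 adjusted over the list alone. Xenobiotic metabolism genes averaged a log2 fold change of -1.29 (camera adjusted p = 9.5e-09, or 0.436 with an estimated correlation; fry adjusted p = 0.00765). Falls were found for Cyp2c55 (-4.23 ± 0.24), Cyp2c66 (-3.19 ± 0.26) and Cyp2c29 (-3.40 ± 0.54), members of a cytochrome P450 family whose similar copies can share reads. Nqo1, a quinone reductase, was at -2.63 ± 0.17 (quasi-likelihood adjusted p = 1.9e-04). The list of glutathione and NRF2 targets fell as well, with 1 higher and 8 lower of 21 tested members, and 1 and 10 adjusted over the list alone. Glutathione and NRF2 targets averaged a log2 fold change of -0.53 (camera adjusted p = 8.7e-04, or 0.436 with an estimated correlation; fry adjusted p = 0.00473). Among them were G6pdx, the entry enzyme of the pentose phosphate pathway (-1.32 ± 0.14), Gpx2, a gut glutathione peroxidase (-2.12 ± 0.25), and Ugdh (-1.34 ± 0.23). Outside the lists, Aqp3, a water and glycerol channel, fell (-3.71 ± 0.31), as did Enpp7, the intestinal alkaline sphingomyelinase (-3.12 ± 0.60). So did Dnah2 (-3.97 ± 0.33) and Sprr2a3 (-3.21 ± 0.67), of which Sprr2a3 can share reads with its close copies.

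The list of carbohydrate digestion and sugar transport fell, with 1 higher and 5 lower of 16 tested members, and 1 and 9 adjusted over the list alone. Carbohydrate and sugar genes averaged a log2 fold change of -0.58 (camera adjusted p = 0.00198, or 0.740 with an estimated correlation; fry adjusted p = 0.120). The hexose transporters Slc2a7 (-2.65 ± 0.31), Slc2a5 (-1.84 ± 0.23) and Slc2a2 (-1.43 ± 0.22) and Fbp1, of gluconeogenesis (-2.15 ± 0.35), fell, and so did the sugar sensor Slc5a4a (-3.14 ± 0.29). The brush border cotransporter Slc5a1 and sucrase-isomaltase did not pass, with Slc5a1 at -0.22 ± 0.26 and Sis at -0.71 ± 0.20 (quasi-likelihood adjusted p = 0.0624 to 0.624). Peptide digestion and amino acid transport fell, with 1 higher and 5 lower of 26 tested members, and 1 and 5 adjusted over the list alone. Peptide and amino acid genes averaged a log2 fold change of -0.64 (camera adjusted p = 5.7e-05, or 0.713 with an estimated correlation; fry adjusted p = 0.0725). The amino acid transporters Slc36a1 (-2.01 ± 0.27) and Slc43a2 (-1.61 ± 0.23) and the peptidase Xpnpep2 (-1.89 ± 0.28) fell. Anpep, an aminopeptidase, went from 3941 ± 887 to 1246 ± 163 CPM (-1.66 ± 0.28). Fabp2, the intestinal fatty acid binding protein, fell (-2.26 ± 0.46). The peptide transporter Slc15a1, Fabp1 and Apoa4 did not pass, with Slc15a1 at -1.08 ± 0.41, Fabp1 at 0.40 ± 0.22 and Apoa4 at -0.72 ± 0.57 (quasi-likelihood adjusted p = 0.131 to 0.444).

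Lists of cholesterol and fatty acid synthesis, glycolysis and oxidative phosphorylation fell in TPN by camera but passed in no case with an estimated correlation. Cholesterol synthesis and uptake had 0 higher and 6 lower of 26 tested members, and 0 and 12 adjusted over the list alone. Cholesterol genes averaged a log2 fold change of -0.64 (camera adjusted p = 9.6e-07, or 0.524 with an estimated correlation; fry adjusted p = 0.0321). They included Insig1 (-0.94 ± 0.16), Mvk (-1.74 ± 0.29), Fdps (-1.45 ± 0.30) and Dhcr7 (-1.08 ± 0.24). Fatty acid synthesis had 1 higher and 5 lower of 21 tested members, and 1 and 7 adjusted over the list alone. Fatty acid synthesis genes averaged a log2 fold change of -0.57 (camera adjusted p = 0.0290, or 0.737 with an estimated correlation; fry adjusted p = 0.0950). Malic enzyme Me1 (-2.22 ± 0.19), the citrate carrier Slc25a1 (-1.33 ± 0.18) and Elovl1 (-0.64 ± 0.12) and Scd2 (-1.48 ± 0.30) fell. The camera call of fatty acid synthesis was lost without sham replicate 3 (mean -0.24), and the mean was -0.88 without sham replicate 2 and -0.88 without TPN replicate 2. Fasn, the fatty acid synthase, did not pass, with Fasn at -0.78 ± 0.58 (quasi-likelihood adjusted p = 0.421). Glycolysis had 0 higher and 5 lower of 19 tested members, and 1 and 6 adjusted over the list alone. Glycolysis genes averaged a log2 fold change of -0.44 (camera adjusted p = 0.0105, or 0.524 with an estimated correlation; fry adjusted p = 0.0170). The enzymes Eno1 (-0.97 ± 0.18), Gapdh (-1.03 ± 0.20) and Ldha (-0.72 ± 0.18) and the lactate carrier Slc16a3 (-2.05 ± 0.39) fell. The glycolysis call was lost with the smooth muscle covariate (mean -0.33, camera adjusted p = 0.0510). Oxidative phosphorylation had 1 higher and 7 lower of 40 tested members, and 1 and 14 adjusted over the list alone. Oxidative phosphorylation genes averaged a log2 fold change of -0.27 (camera adjusted p = 0.00785, or 0.740 with an estimated correlation; fry adjusted p = 0.146). Examples were Ndufv1 (-0.70 ± 0.14), Ndufb10 (-0.66 ± 0.14), Cyc1 (-0.81 ± 0.17) and Atp5a1 (-0.71 ± 0.16).

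Interferon response fell in TPN, with 0 higher and 11 lower of 31 tested members, and 0 and 17 adjusted over the list alone. Interferon response genes averaged a log2 fold change of -0.88 (camera adjusted p = 1.8e-08, or 0.436 with an estimated correlation; fry adjusted p = 0.0214). The members with the smallest adjusted p were the interferon-induced GTPases Ifi47 (-0.94 ± 0.14), Igtp (-1.66 ± 0.25), Irgm1 (-0.93 ± 0.17) and Gbp7 (-0.65 ± 0.13). The list of inflammatory cytokines and chemokines rose, with 4 higher and 1 lower of 16 tested members, and 5 and 2 adjusted over the list alone. Inflammatory genes averaged a log2 fold change of 0.91 (camera adjusted p = 0.0477, or 0.663 with an estimated correlation; fry adjusted p = 0.0582). That camera call was lost without sham replicate 3, TPN replicate 1, TPN replicate 3 or starvation replicate 3, with means of 1.01, 0.76, 0.73 and 0.99. It was also lost with upper quartile factors (mean 1.00, camera adjusted p = 0.0896) and with library totals only (mean 1.10, camera adjusted p = 0.118), where the means were not smaller. Further losses came without the filter, in the fit of only the groups compared, with the replicate block, with the smooth muscle covariate and without sham replicate 2 and starvation replicate 3, and the call held in 8 of 21 alternatives. Il1b went from 2.58 ± 0.774 to 12.3 ± 2.10 CPM, and the chemokines Ccl2 (2.75 ± 0.69) and Cxcl5 (2.78 ± 0.73) rose. Cxcl1, a neutrophil attractant, had 3 reads in sham and 107 in TPN, a ratio of 34.1 with a 95% counting interval of 11.4 to 168.

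Stromal lists were lower in TPN by camera, but not with an estimated correlation, in a comparison in which sham replicate 2 held the most muscle. Fibroblast and matrix markers had 0 higher and 7 lower of 18 tested members, and 0 and 12 adjusted over the list alone. Fibroblast and matrix markers averaged a log2 fold change of -1.24 (camera adjusted p = 4.8e-05, or 0.683 with an estimated correlation; fry adjusted p = 0.118). The collagens Col3a1 (-2.66 ± 0.36), Col1a1 (-2.18 ± 0.41) and Col1a2 (-1.90 ± 0.40) and Fbln1 (-0.94 ± 0.19) fell. Smooth muscle markers had 0 higher and 0 lower of 15 tested members, and 0 and 14 adjusted over the list alone. Smooth muscle markers averaged a log2 fold change of -2.36 (camera adjusted p = 2.0e-04, or 0.740 with an estimated correlation; fry adjusted p = 0.285). No member passed over all genes, with Actg2 at -3.32 ± 0.93, Tpm2 at -3.20 ± 0.94, Acta2 at -2.99 ± 0.89 and Mylk at -2.25 ± 0.69 (quasi-likelihood adjusted p = 0.0572 to 0.0729). Without sham replicate 2 the means of the fibroblast and smooth muscle lists were -0.75 and -0.66. Acta1, a muscle actin (-4.34 ± 0.66), and Dbp, a clock output gene (-1.54 ± 0.30), fell. The sentinel lineage markers did not pass, with Lgr5 at -0.37 ± 0.52, Olfm4 at -0.30 ± 0.52, Mki67 at -0.40 ± 0.59, Lyz1 at 0.16 ± 0.43, Muc2 at 0.32 ± 0.22, Chga at 0.45 ± 0.14 and Dclk1 at 0.42 ± 0.30 (quasi-likelihood adjusted p = 0.0727 to 0.842), which mark stem, cycling, Paneth, goblet, endocrine and tuft cells. Neither did the amino acid response gene Asns nor the lectin Reg3g, with Asns at 0.49 ± 0.48 and Reg3g at -1.09 ± 0.48 (quasi-likelihood adjusted p = 0.176 to 0.542).

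Scaling by library totals alone moved the median of all genes by 0.189 on the log2 scale and gave 651 genes higher and 573 lower in TPN, 46.8% lower in place of 59.6%; upper quartile factors gave 48.6%. Single libraries moved the counts as well: 83 genes rose and 133 fell without TPN replicate 1, 98 and 125 without TPN replicate 2, and 113 and 129 without TPN replicate 3. Without sham replicates 1 and 3 the counts were 216 and 347, and 142 and 253. Without starvation replicate 2 they were 259 and 431, and without starvation replicate 3 they were 1477 and 1705. With sham replicate 2 and starvation replicate 3 left out together, 2232 rose and 2193 fell. Of the 62 named genes that passed, 28 kept their call with any 1 library left out, among them Fkbp5, Zbtb16, Cyp1a1, Cyp2c55, Nqo1, Slc2a7 and Slc36a1. Another 14, among them Lrg1, Sprr2a3, Gapdh, Ldha, Cxcl1, Ccl2 and Cxcl5, lost it in at least 5 of the 9 fits.

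**Figure D2:**
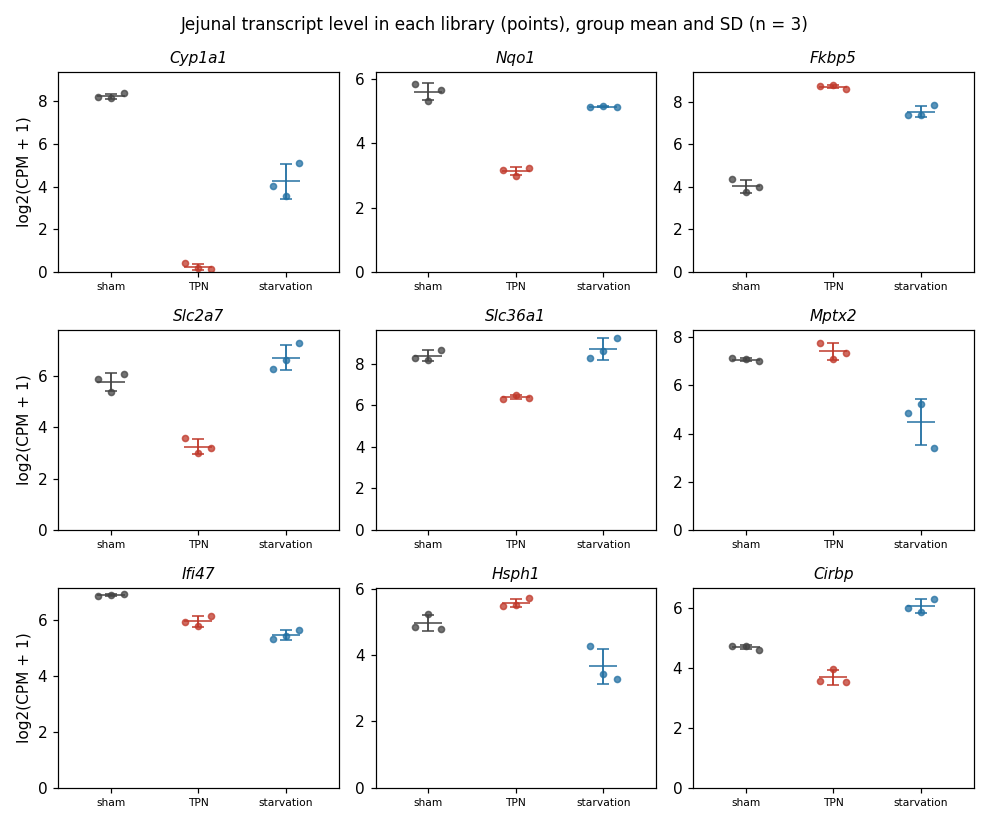
Transcript level as log2(CPM + 1) (y axis) of 9 genes in each library of the 3 groups (x axis), with points for libraries and the bar and whiskers for group mean and SD (n = 3). Cyp1a1 is near 0 in TPN (0.176 CPM) and Slc2a7 is lowest in TPN (8.68 CPM), while Mptx2 is lowest in starvation (24.5 CPM) and Cirbp, chosen after its values were seen, highest there (66.5 CPM).

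Starvation was compared with sham to ask what changes when nutrients come by neither route, as the treatment name implies. Procedure may differ here too. Among genes with an adjusted p under 0.05, a mean log2 CPM of at least 3 and no overlap between the groups, the metallothioneins rose most, Mt2 from 5.12 ± 2.66 to 239 ± 104 CPM (5.54 ± 0.44) and Mt1 from 19.95 ± 2.65 to 358 ± 206 CPM (4.17 ± 0.40). The glucocorticoid-induced Fkbp5 (3.57 ± 0.23) and Zbtb16 (3.53 ± 0.40) and the fasting genes Angptl4 (2.82 ± 0.29) and Pdk4 (2.09 ± 0.32) rose, and Cyp1a1 fell to 20.04 ± 12.3 CPM (-3.91 ± 0.41). By camera and fry, the lists of Paneth cell markers, interferon response and heat shock fell, and no list passed with an estimated correlation. Over all genes 374 rose and 167 fell by the edgeR quasi-likelihood test, 257 and 103 of them at least 2-fold. All 541 had groups that did not overlap, against 25.1% of all genes and a chance share of 10%.

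The glucocorticoid response list rose in starvation, with 7 higher and 0 lower of 16 tested members, and 8 and 0 adjusted over the list alone. Glucocorticoid response genes averaged a log2 fold change of 1.28 (camera adjusted p = 4.1e-05, or 0.436 with an estimated correlation; fry adjusted p = 0.00473). Other large rises were in Ano3 (3.80 ± 0.54) and Extl1 (2.67 ± 0.30), the mannose-binding lectin Mbl2 (2.93 ± 0.53) and the stress ligands Raet1e (2.63 ± 0.57) and H60b (2.54 ± 0.56), which overlap each other on the genome. The circadian clock list was higher, with 4 higher and 0 lower of 19 tested members, and 6 and 1 adjusted over the list alone. Circadian clock genes averaged a log2 fold change of 0.38 (camera adjusted p = 0.0386, or 0.740 with an estimated correlation; fry adjusted p = 0.195). The repressors Per3 (1.16 ± 0.20), Ciart (2.37 ± 0.41), Per1 (1.2 ± 0.21) and Cry2 (0.98 ± 0.23) rose, and the camera call was lost without sham replicate 1, sham replicate 3 or starvation replicate 3, with means of 0.35, 0.35 and 0.19. Peptide digestion and amino acid transport was higher, with 1 higher and 0 lower of 26 tested members, and 3 and 0 adjusted over the list alone. Peptide and amino acid genes averaged a log2 fold change of 0.51 (camera adjusted p = 6.7e-04, or 0.737 with an estimated correlation; fry adjusted p = 0.176). Slc6a20a, a proline carrier, rose (1.10 ± 0.24), and other carriers did not pass, with Slc7a9 at 1.62 ± 0.41, Slc7a8 at 0.85 ± 0.23 and Slc6a19 at 1.19 ± 0.38 (quasi-likelihood adjusted p = 0.0628 to 0.112). This call was lost without starvation replicate 3, the library with the most villus tip transcripts (mean 0.22).

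Paneth cell markers fell in starvation, with 0 higher and 6 lower of 15 tested members, and 0 and 10 adjusted over the list alone. Paneth cell markers averaged a log2 fold change of -1.75 (camera adjusted p = 9.6e-10, or 0.436 with an estimated correlation; fry adjusted p = 0.0153). The defensins Defa24 (-3.17 ± 0.40), Defa30 (-2.72 ± 0.47) and Defa5 (-2.92 ± 0.35) are near-identical copies whose reads can be shared. Mptx2, a mucosal pentraxin, fell from 134 ± 6.01 to 24.5 ± 13.6 CPM, and the lectin Itln1 (-1.47 ± 0.22) fell too. Lysozyme did not pass, with Lyz1 at -1.14 ± 0.43 (quasi-likelihood adjusted p = 0.157). Stem cell markers were lower by camera, beside the low crypt markers of starvation replicate 3, with 0 higher and 0 lower of 23 tested members, and 0 and 0 adjusted over the list alone. Stem cell markers averaged a log2 fold change of -0.41 (camera adjusted p = 0.00297, or 0.740 with an estimated correlation; fry adjusted p = 0.372). Among them were Smoc2 at -1.35 ± 0.45, Rgmb at -0.81 ± 0.27, Tnfrsf19 at -0.99 ± 0.35 and Bmi1 at -0.52 ± 0.18 (quasi-likelihood adjusted p = 0.123 to 0.138). Cell cycle genes were lower by camera, with 0 higher and 1 lower of 44 tested members, and 0 and 1 adjusted over the list alone. Cell cycle genes averaged a log2 fold change of -0.45 (camera adjusted p = 0.00110, or 0.863 with an estimated correlation; fry adjusted p = 0.504). Cyclin D1, Ccnd1 (-1.46 ± 0.30), fell, with Birc5 at -0.77 ± 0.25, Mcm4 at -0.76 ± 0.26 and Pcna at -0.34 ± 0.13 (quasi-likelihood adjusted p = 0.109 to 0.148). Both camera calls, of stem cell and cell cycle lists, were lost without starvation replicate 3 (means -0.14 and -0.16). Without starvation replicate 1 the means were -0.73 and -0.76, and the cell cycle mean was -0.26 and -0.71 without sham replicates 1 and 2.

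Interferon response fell in starvation, with 0 higher and 13 lower of 31 tested members, and 0 and 17 adjusted over the list alone. Interferon response genes averaged a log2 fold change of -1.05 (camera adjusted p = 1.5e-15, or 0.397 with an estimated correlation; fry adjusted p = 0.00765). The GTPases Ifi47 (-1.44 ± 0.15) and Gbp6 (-1.89 ± 0.26), the chemokine Cxcl9 (-1.59 ± 0.22) and Ifi44 (-2.54 ± 0.34) fell. Outside that list, the membrane proteins Ifitm3 (-2.76 ± 0.35) and Ifitm2 (-2.06 ± 0.40) fell. Heat shock genes fell, with 0 higher and 5 lower of 20 tested members, and 0 and 11 adjusted over the list alone. Heat shock genes averaged a log2 fold change of -0.83 (camera adjusted p = 2.6e-08, or 0.220 with an estimated correlation; fry adjusted p = 0.00473). Chaperones and their partners Hspa4 (-0.81 ± 0.12), Hsph1 (-1.30 ± 0.27), Ahsa1 (-0.89 ± 0.19) and Hspe1 (-1.08 ± 0.24) fell. Endoplasmic reticulum chaperones were lower by camera, with 0 higher and 3 lower of 20 tested members, and 1 and 8 adjusted over the list alone. Endoplasmic reticulum chaperones averaged a log2 fold change of -0.45 (camera adjusted p = 6.2e-05, or 0.590 with an estimated correlation; fry adjusted p = 0.0539). Examples were Pdia3 (-1.03 ± 0.15), Sdf2l1 (-0.88 ± 0.17) and Calr (-1.0 ± 0.20), with Pdia6 at -1.04 ± 0.25 (quasi-likelihood adjusted p = 0.0520) not passing. Outside the lists, Paqr9 (-3.79 ± 0.45) and Rpl35a (-2.08 ± 0.46) fell, of which Rpl35a, a ribosomal protein gene, can share reads with its pseudogenes.

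Lipid synthesis lists were lower by camera in starvation, but not with an estimated correlation. Cholesterol synthesis and uptake had 0 higher and 2 lower of 26 tested members, and 0 and 4 adjusted over the list alone. Cholesterol genes averaged a log2 fold change of -0.32 (camera adjusted p = 0.00362, or 0.737 with an estimated correlation; fry adjusted p = 0.172). Of its genes Hmgcs1 (-0.72 ± 0.14) and Insig1 (-0.75 ± 0.16) passed, with Idi1 at -1.15 ± 0.30 and Cyp51 at -0.75 ± 0.21 (quasi-likelihood adjusted p = 0.0689 to 0.0766). Fatty acid synthesis had 0 higher and 0 lower of 21 tested members, and 0 and 0 adjusted over the list alone. Fatty acid synthesis genes averaged a log2 fold change of -0.53 (camera adjusted p = 0.00621, or 0.663 with an estimated correlation; fry adjusted p = 0.120). No member passed, with Scd2 at -1.11 ± 0.29, Elovl6 at -1.15 ± 0.33, Elovl5 at -0.56 ± 0.21 and Fads1 at -0.86 ± 0.34 (quasi-likelihood adjusted p = 0.0691 to 0.166). The cholesterol call was lost without sham replicate 1 (mean -0.22), and the fatty acid call without sham replicate 3 (mean -0.20).

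Stromal lists were lower by camera in starvation too, but not with an estimated correlation, with the same muscle-rich sham replicate 2 in the comparison. Fibroblast and matrix markers had 0 higher and 2 lower of 18 tested members, and 0 and 7 adjusted over the list alone. Fibroblast and matrix markers averaged a log2 fold change of -1.14 (camera adjusted p = 2.0e-06, or 0.590 with an estimated correlation; fry adjusted p = 0.0962). The collagens Col3a1 (-2.20 ± 0.36) and Col1a1 (-1.76 ± 0.41) fell, with Sparc at -1.86 ± 0.44 and Fn1 at -0.92 ± 0.26 (quasi-likelihood adjusted p = 0.0514 to 0.0816). Smooth muscle markers had 0 higher and 0 lower of 15 tested members, and 0 and 0 adjusted over the list alone. Smooth muscle markers averaged a log2 fold change of -2.03 (camera adjusted p = 5.7e-04, or 0.740 with an estimated correlation; fry adjusted p = 0.382). No member passed, with Synm at -2.62 ± 0.86, Cald1 at -2.20 ± 0.73, Actg2 at -2.70 ± 0.90 and Mylk at -1.86 ± 0.68 (quasi-likelihood adjusted p = 0.119 to 0.145), while Acta1 (-3.01 ± 0.61) fell. Without sham replicate 2 the means of the fibroblast and smooth muscle lists were -0.65 and -0.32. The smooth muscle call was then lost, with a camera adjusted p of 0.0733 (range over its alternatives 1.5e-06 to 0.890).

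Myeloid, endothelial and enteric neuron lists were lower by camera in starvation, but not with an estimated correlation. Myeloid cell markers had 0 higher and 0 lower of 20 tested members, and 0 and 0 adjusted over the list alone. Myeloid cell markers averaged a log2 fold change of -0.54 (camera adjusted p = 0.00363, or 0.659 with an estimated correlation; fry adjusted p = 0.120). Endothelial markers had 0 higher and 0 lower of 16 tested members, and 0 and 0 adjusted over the list alone. Endothelial markers averaged a log2 fold change of -0.55 (camera adjusted p = 0.0265, or 0.740 with an estimated correlation; fry adjusted p = 0.370). Enteric neuron and glia markers had 0 higher and 0 lower of 18 tested members, and 0 and 0 adjusted over the list alone. Enteric neuron and glia markers averaged a log2 fold change of -0.73 (camera adjusted p = 0.0146, or 0.740 with an estimated correlation; fry adjusted p = 0.329). No member passed over all genes, with Cd68 at -0.76 ± 0.25, Itgam at -0.67 ± 0.23, Flt4 at -1.56 ± 0.46, Cldn5 at -1.70 ± 0.61, Uchl1 at -1.35 ± 0.52 and Gfap at -1.95 ± 0.81 (quasi-likelihood adjusted p = 0.0924 to 0.186). These 3 calls were lost without starvation replicate 3 (means -0.45, -0.26 and -0.58), and the endothelial call also without sham replicate 3 (mean -0.54). The myeloid mean was -0.22 without the muscle-rich sham replicate 2 and -0.10 without both libraries. The neuron call was also lost with the smooth muscle covariate (mean -0.47, camera adjusted p = 0.103).

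The sentinel genes of absorption did not pass in starvation, with Apoa4 at -0.00 ± 0.56, Fabp1 at 0.49 ± 0.22, Fabp2 at -0.10 ± 0.44, Sis at -0.19 ± 0.20, Slc5a1 at 0.29 ± 0.26 and Slc15a1 at 0.99 ± 0.41 (quasi-likelihood adjusted p = 0.188 to 0.998). The sentinel lineage markers did not pass either, with Lgr5 at 0.03 ± 0.51, Olfm4 at -0.93 ± 0.52, Mki67 at -0.59 ± 0.59, Muc2 at 0.05 ± 0.22, Chga at -0.10 ± 0.14 and Dclk1 at 0.32 ± 0.30 (quasi-likelihood adjusted p = 0.312 to 0.984). Nor did other sentinel genes of metabolism, defence and the clock, with Cpt1a at -0.22 ± 0.32, Fasn at -1.44 ± 0.59, Asns at 0.15 ± 0.48, Reg3g at -1.79 ± 0.48 and Dbp at -0.09 ± 0.29 (quasi-likelihood adjusted p = 0.0743 to 0.880). Fitted without the TPN libraries, edgeR called 2 genes higher and 0 lower in starvation. In the fit of all 9 libraries 3430 genes had an unadjusted p under 0.05, and DESeq2 called 931 higher and 607 lower. Genes rose and fell in the numbers 114 and 62 without sham replicate 1, 164 and 99 without sham replicate 2, and 22 and 10 without sham replicate 3. Without TPN replicates 1, 2 and 3 they were 75 and 28, 83 and 34, and 102 and 38. Without starvation replicates 1, 2 and 3 they were 290 and 80, 31 and 16, and 945 and 794. With sham replicate 2 and starvation replicate 3 left out together, 1612 rose and 1337 fell. Of the 43 named genes that passed, 12 kept their call with any 1 library left out, among them Mt2, Mt1, Fkbp5, Zbtb16, Angptl4, Cyp1a1, Ifitm3 and Ifi47. Another 19, among them Raet1e, H60b, Per1, Cry2, Hsph1, Calr and Ccnd1, lost it in at least 5 of the 9 fits.

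TPN was compared with starvation, both unfed by gut per their names, to ask whether the responses differ and what blood nutrients change. Whether starved mice had surgery or infusion is not stated, so procedure may differ too. By camera and fry, lists of peptide and sugar uptake and xenobiotic metabolism were lower in TPN, and lists of Paneth cell markers, heat shock and inflammatory genes were higher. No list passed with an estimated correlation. Slc2a7 was at 8.68 ± 2.07 CPM in TPN and 109.8 ± 40.0 in starvation (-3.65 ± 0.32). Mptx2 was at 172 ± 41.0 and 24.5 ± 13.6 CPM (2.81 ± 0.41). Over all genes 285 were higher and 572 lower in TPN by the edgeR quasi-likelihood test, 169 and 363 of them at least 2-fold. All 857 had groups that did not overlap, against 33.6% of all genes and a chance share of 10%.

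Peptide digestion and amino acid transport was lower in TPN than in starvation, with 0 higher and 12 lower of 26 tested members, and 1 and 22 adjusted over the list alone. Peptide and amino acid genes averaged a log2 fold change of -1.15 (camera adjusted p = 2.6e-11, or 0.436 with an estimated correlation; fry adjusted p = 0.0106). Examples were Xpnpep2 (-2.52 ± 0.28), Slc36a1 (-2.39 ± 0.27), Slc43a2 (-1.83 ± 0.23) and Slc6a20a (-1.50 ± 0.24) and the peptide transporter Slc15a1 (-2.07 ± 0.43). Carbohydrate digestion and sugar transport was lower, with 1 higher and 7 lower of 16 tested members, and 1 and 9 adjusted over the list alone. Carbohydrate and sugar genes averaged a log2 fold change of -0.94 (camera adjusted p = 9.6e-06, or 0.673 with an estimated correlation; fry adjusted p = 0.0482). Hexose transporters Slc2a5 (-1.82 ± 0.23) and Slc2a2 (-1.55 ± 0.23) were lower, as was Slc37a4 (-1.23 ± 0.20). Sis at -0.52 ± 0.20 and Slc5a1 at -0.51 ± 0.26 did not pass (quasi-likelihood adjusted p = 0.164 to 0.279). Lipid absorption and chylomicron assembly was lower by camera, with 0 higher and 5 lower of 25 tested members, and 0 and 10 adjusted over the list alone. Lipid absorption genes averaged a log2 fold change of -0.72 (camera adjusted p = 1.9e-04, or 0.740 with an estimated correlation; fry adjusted p = 0.271). The acyltransferases Dgat1 (-1.56 ± 0.29) and Soat2 (-1.44 ± 0.29) and Tm6sf2 (-1.04 ± 0.22) and Fabp2 (-2.16 ± 0.46) were lower, with Apoa4 at -0.72 ± 0.57 and Fabp1 at -0.09 ± 0.22 (quasi-likelihood adjusted p = 0.489 to 0.846). The lipid absorption call was lost without starvation replicate 3, which had the most villus tip transcripts (mean -0.18). Outside the lists, the sugar sensor Slc5a4a (-3.90 ± 0.30), the channels Aqp3 (-3.86 ± 0.31) and Aqp7 (-3.37 ± 0.56), the nucleoside carrier Slc28a1 (-3.44 ± 0.28) and Enpp7 (-3.79 ± 0.61) and Susd2 (-3.42 ± 0.64) were lower.

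Xenobiotic metabolism was lower in TPN than in starvation, with 0 higher and 14 lower of 32 tested members, and 1 and 20 adjusted over the list alone. Xenobiotic metabolism genes averaged a log2 fold change of -1.24 (camera adjusted p = 1.7e-09, or 0.436 with an estimated correlation; fry adjusted p = 0.00765). Lower genes included Cyp1a1 (-6.69 ± 0.59), Gstm1 (-2.17 ± 0.16), Nqo1 (-2.13 ± 0.17), Cyp2c29 (-4.62 ± 0.56) and Cyp2c55 (-3.20 ± 0.24). Glutathione and NRF2 targets were lower, with 1 higher and 6 lower of 21 tested members, and 1 and 9 adjusted over the list alone. Glutathione and NRF2 targets averaged a log2 fold change of -0.44 (camera adjusted p = 0.0105, or 0.524 with an estimated correlation; fry adjusted p = 0.0153). The enzymes Gclc (-1.11 ± 0.17), G6pdx (-0.84 ± 0.14) and Ugdh (-1.22 ± 0.23) were lower. Cholesterol synthesis and uptake was lower by camera, with 0 higher and 3 lower of 26 tested members, and 0 and 3 adjusted over the list alone. Cholesterol genes averaged a log2 fold change of -0.32 (camera adjusted p = 0.0360, or 0.740 with an estimated correlation; fry adjusted p = 0.268). They included Mvk (-1.40 ± 0.29), Msmo1 (-1.33 ± 0.31) and Dhcr7 (-1.0 ± 0.24). Circadian clock genes were lower by camera, with 1 higher and 4 lower of 19 tested members, and 1 and 8 adjusted over the list alone. Circadian clock genes averaged a log2 fold change of -0.47 (camera adjusted p = 0.0395, or 0.740 with an estimated correlation; fry adjusted p = 0.194). Among them were Per3 (-1.30 ± 0.20), Ciart (-2.70 ± 0.42), Dbp (-1.45 ± 0.30) and Cry2 (-1.11 ± 0.23). Red blood cell markers were lower by camera, with 0 higher and 1 lower of 5 tested members, and 0 and 3 adjusted over the list alone. Red blood cell markers averaged a log2 fold change of -1.94 (camera adjusted p = 0.0165, or 0.737 with an estimated correlation; fry adjusted p = 0.118). Haemoglobin genes are copies whose reads can be shared: Hba-a1 (-3.01 ± 0.64) was lower, with Hba-a2 at -2.86 ± 0.86 and Hbb-bs at -1.92 ± 0.66 (quasi-likelihood adjusted p = 0.0862 to 0.123). The NRF2, clock and red blood cell calls were lost without starvation replicate 3 (means -0.33, -0.25 and -1.55). The cholesterol call was lost without starvation replicate 1 or 2, where the mean was still -0.30 and -0.29. It was also lost with upper quartile factors (mean -0.24, camera adjusted p = 0.0605) library totals only (mean -0.18, camera adjusted p = 0.11) or DESeq2 (mean -0.31, camera adjusted p = 0.0598).

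Paneth cell markers were higher in TPN than in starvation, with 9 higher and 0 lower of 15 tested members, and 14 and 0 adjusted over the list alone. Paneth cell markers averaged a log2 fold change of 2.07 (camera adjusted p = 2.9e-12, or 0.436 with an estimated correlation; fry adjusted p = 0.00765). The defensins Defa24 (3.32 ± 0.40), Defa30 (2.79 ± 0.47), Defa5 (3.00 ± 0.35) and Defa17 (2.25 ± 0.36) share reads with near-identical copies, and Mmp7, the protease that activates defensins, was higher too (2.40 ± 0.50). Against sham the list did not pass in TPN, with 1 higher and 0 lower of 15 tested members, and 1 and 0 adjusted over the list alone, and a camera adjusted p of 0.146. Heat shock genes were higher, with 11 higher and 0 lower of 20 tested members, and 14 and 1 adjusted over the list alone. Heat shock genes averaged a log2 fold change of 0.89 (camera adjusted p = 2.6e-09, or 0.220 with an estimated correlation; fry adjusted p = 0.00269). Chaperones and their partners Chordc1 (0.82 ± 0.11), Hspa4 (0.87 ± 0.12), Hsph1 (1.91 ± 0.27) and Hspa4l (1.30 ± 0.20) were higher. Endoplasmic reticulum chaperones were higher by camera, with 2 higher and 0 lower of 20 tested members, and 6 and 0 adjusted over the list alone. Endoplasmic reticulum chaperones averaged a log2 fold change of 0.32 (camera adjusted p = 0.00178, or 0.737 with an estimated correlation; fry adjusted p = 0.118). Of these Sdf2l1 (0.77 ± 0.17) and Pdia3 (0.66 ± 0.15) passed, with Pdia6 at 0.99 ± 0.25 and Hsp90b1 at 0.69 ± 0.18 (quasi-likelihood adjusted p = 0.0501 to 0.0575). The glucocorticoid response list was higher, with 5 higher and 0 lower of 16 tested members, and 6 and 1 adjusted over the list alone. The mean log2 fold change was 0.69 (camera adjusted p = 0.00138, or 0.508 with an estimated correlation, and fry adjusted p = 0.0367). Examples were Ddit4 (1.49 ± 0.21), Fkbp5 (1.17 ± 0.20) and Errfi1 (1.11 ± 0.22). The siderophore-binding Lcn2 (5.23 ± 0.98) made up much of the list mean. The fasting gene Pdk4 did not pass, at 0.62 ± 0.31 (quasi-likelihood adjusted p = 0.260).

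Inflammatory cytokines and chemokines were higher in TPN than in starvation, with 4 higher and 0 lower of 16 tested members, and 7 and 1 adjusted over the list alone. Inflammatory genes averaged a log2 fold change of 1.11 (camera adjusted p = 0.0131, or 0.524 with an estimated correlation; fry adjusted p = 0.0173). Examples were Il1b (3.05 ± 0.38), Ccl2 (3.96 ± 0.76), Cxcl5 (3.71 ± 0.78) and Cxcl1 (4.48 ± 0.96). Secreted antimicrobial defence was higher, with 3 higher and 0 lower of 11 tested members, and 4 and 0 adjusted over the list alone. Antimicrobial defence genes averaged a log2 fold change of 1.55 (camera adjusted p = 0.00390, or 0.436 with an estimated correlation; fry adjusted p = 0.0370). Serum amyloid Saa3 was at 74.7 ± 8.37 and 0.617 ± 1.07 CPM (7.06 ± 1.08) and Lypd8 (1.22 ± 0.27) was higher, with Reg3a at 1.97 ± 0.57 (quasi-likelihood adjusted p = 0.0746) not passing. Myeloid cell markers were higher by camera, with 4 higher and 0 lower of 20 tested members, and 5 and 0 adjusted over the list alone. Myeloid cell markers averaged a log2 fold change of 0.86 (camera adjusted p = 3.4e-04, or 0.524 with an estimated correlation; fry adjusted p = 0.0582). Among them were Itgam (1.88 ± 0.23), Cxcr2 (3.95 ± 0.65) and Fcer1g (1.30 ± 0.32). S100a8, a neutrophil protein, had 100 reads in TPN and 3 in starvation, a ratio of 30.9 with a 95% counting interval of 10.3 to 153. The inflammatory call was lost without starvation replicate 3 (mean 1.01).

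Interferon response was higher by camera in TPN than in starvation, with 4 higher and 0 lower of 31 tested members, and 7 and 0 adjusted over the list alone. Interferon response genes averaged a log2 fold change of 0.18 (camera adjusted p = 0.0150, or 0.740 with an estimated correlation; fry adjusted p = 0.329). Higher members were Gbp6 (1.91 ± 0.26), Cxcl9 (1.16 ± 0.22), Ifi44 (1.37 ± 0.34) and Bst2 (1.27 ± 0.32). Outside that list, Ifitm3 (2.73 ± 0.35) and Ifitm2 (2.40 ± 0.40) and Gm45717 (2.35 ± 0.41), which overlaps Ifitm2 on the same strand, were higher. So were Serpina3n (3.62 ± 0.60), Gm45871 (2.58 ± 0.23) and Olfr1033 (2.45 ± 0.55). Endocrine markers were higher, with 2 higher and 0 lower of 22 tested members, and 2 and 0 adjusted over the list alone. Endocrine markers averaged a log2 fold change of 0.27 (camera adjusted p = 0.0105, or 0.436 with an estimated correlation; fry adjusted p = 0.0321). Somatostatin and chromogranin passed, Sst (0.99 ± 0.23) and Chga (0.55 ± 0.14), with Reg4 at 0.70 ± 0.24 and Gcg at 1.56 ± 0.63 (quasi-likelihood adjusted p = 0.120 to 0.174). The interferon call was lost without starvation replicate 1 or 2 (means 0.06 and 0.08), with a mean of 0.56 without starvation replicate 3, and the endocrine call without starvation replicate 1 (mean 0.23).

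Stem cell, endothelial and enteric neuron lists were higher by camera in TPN than in starvation, but not with an estimated correlation, with no member passing over all genes. Stem cell markers had 0 higher and 0 lower of 23 tested members, and 0 and 0 adjusted over the list alone. Stem cell markers averaged a log2 fold change of 0.40 (camera adjusted p = 0.00621, or 0.740 with an estimated correlation; fry adjusted p = 0.393). Endothelial markers had 0 higher and 0 lower of 16 tested members, and 0 and 0 adjusted over the list alone. Endothelial markers averaged a log2 fold change of 0.41 (camera adjusted p = 0.0231, or 0.740 with an estimated correlation; fry adjusted p = 0.382). Enteric neuron and glia markers had 0 higher and 0 lower of 18 tested members, and 0 and 0 adjusted over the list alone. Enteric neuron and glia markers averaged a log2 fold change of 0.70 (camera adjusted p = 0.00518, or 0.740 with an estimated correlation; fry adjusted p = 0.256). Among them were Bmi1 at 0.59 ± 0.18, Prom1 at 0.90 ± 0.30, Lyve1 at 1.44 ± 0.54 and Elavl3 at 1.79 ± 0.56 (quasi-likelihood adjusted p = 0.0945 to 0.148). These calls were lost without starvation replicate 3 (means 0.16, 0.15 and 0.58), the neuron call also without TPN replicate 3 (mean 0.38), and the endothelial call with library totals only (mean 0.49, camera adjusted p = 0.0601) and with DESeq2 (mean 0.43, camera adjusted p = 0.0533). Without starvation replicate 1 the stem cell and neuron means were 0.72 and 1.07, and without starvation replicate 2 the endothelial mean was 0.66. The sentinel lineage markers other than Chga did not pass, with Lgr5 at -0.40 ± 0.52, Olfm4 at 0.63 ± 0.52, Mki67 at 0.19 ± 0.59, Lyz1 at 1.30 ± 0.44, Muc2 at 0.26 ± 0.22 and Dclk1 at 0.10 ± 0.30 (quasi-likelihood adjusted p = 0.114 to 0.884). Other sentinel genes that missed the threshold were Cpt1a at 0.35 ± 0.32, Fasn at 0.66 ± 0.59, Asns at 0.34 ± 0.48 and Reg3g at 0.69 ± 0.47 (quasi-likelihood adjusted p = 0.423 to 0.721).

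The counts for TPN against starvation moved with single libraries. Without TPN replicates 1, 2 and 3, 48 and 111, 47 and 90, and 43 and 81 genes were higher and lower. Without sham replicates 1, 2 and 3 the counts were 177 and 363, 465 and 783, and 171 and 358. Without starvation replicates 2 and 3 they were 143 and 319, and 482 and 593. With sham replicate 2 and starvation replicate 3 left out together, 1500 were higher and 1705 lower. Scaling by library totals moved the median of all genes by 0.143 on the log2 scale. Of the 73 named genes that passed, 26 kept their call with any 1 library left out, among them Cyp1a1, Slc2a7, Slc36a1, Aqp3, Slc28a1, Nqo1, Defa24 and Mptx2. Another 14, among them Sst, Chga, Pdia3, Fcer1g and S100a8, lost it in at least 5 of the 9 fits.

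**Figure D3:**
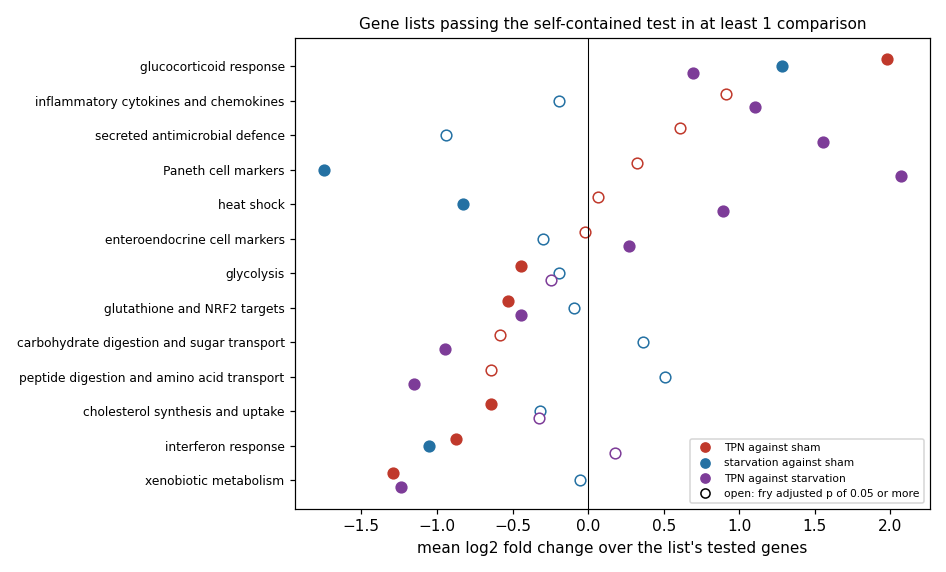
Mean log2 fold change (x axis) of the gene lists (y axis) that passed the fry test in at least 1 comparison, with 1 colour per comparison and filled points where the fry adjusted p was under 0.05. The glucocorticoid response list is above 0 in all comparisons, at 1.98, 1.28 and 0.69, and Paneth cell markers lie at -1.75 in starvation against sham and 2.07 in TPN against starvation.

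Over the whole design 1586 genes differed among the 3 groups by the edgeR quasi-likelihood F test. TPN and starvation shared 149 genes higher and 66 lower against sham, 215 in all. Independent lists would share 13.0 and 8.55, and simulated unchanged groups shared 0. Fkbp5, Zbtb16, Mt1, Mt2, Angptl4 and Pdk4 were higher in both, and Cyp1a1, Ifi47, Col3a1 and Insig1 lower. The log2 fold changes had a covariance of 0.350, against 0.103 in the simulations, a difference of 0.248. Their correlation over genes, which are not independent replicates, was 0.586 against a simulated 0.502, and 68.8% of genes had the same sign against 66.6%. The sham libraries cannot be split, so part of the excess may come from them. Another 5 genes were called in opposite directions, where independent lists would give 24.96. Of the 215 shared genes, 202 did not pass in TPN against starvation. The shared count was 71, 125 and 20 without sham replicates 1, 2 and 3, and 31, 42 and 41 without TPN replicates 1, 2 and 3. It was 26 without starvation replicate 2, 931 without starvation replicate 3 and 1610 without sham replicate 2 and starvation replicate 3. The count over the 3 groups was 793 and 593 without sham replicates 1 and 3, and 298, 286 and 313 without TPN replicates 1, 2 and 3. It was 753 without starvation replicate 2, 3576 without starvation replicate 3 and 5762 without sham replicate 2 and starvation replicate 3.

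On GRCm38, genes with large changes that overlap no other gene of the table were annotated as protein coding. Cyp1a1 lies on chromosome 9, 57687928 to 57703824, plus strand. Fkbp5 lies on chromosome 17, 28399094 to 28517527, minus strand. Slc2a7 lies on chromosome 4, 150148972 to 150168482, plus strand. Mptx2 lies on chromosome 1, 173274382 to 173277777, minus strand. Counts cover whole genes, so exons and UTRs are not separated. The spans of several named genes, introns included, overlap another gene of the table. Exon overlap was not checked, so the counts of these genes may or may not be affected. On the other strand these were Acta1, Ano3, Atp5a1, Ccl2, Ccnd1, Cyp51, Dbp, Dclk1, Elovl1, G6pdx, Gapdh, Gpx2, Hspe1, Lgr5, Pdia3, Pdia6, Slc6a20a and Synm. On the same strand these were Elavl3, Fdps, Gbp6, Gm45717, H60b, Ifi47, Ifitm2, Igtp, Itgam, Per3, Raet1e and Ugdh.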

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

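The tests weighed here were chosen after the values they rest on had been seen, apart from the counts of lists called by fry in other splits of the libraries. In the test of the pancreatic genes, Zg16 was left out of the stated criterion only after the correlation had been seen. Groups of 3 libraries are too small for the test of a single library standing apart, so the results below were picked out because the responses to TPN and to starvation went in opposite directions, each past the threshold, and the contrast of TPN with starvation passed as well. These 5 genes lie outside the rule for named genes and are named after their values were seen.

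Cirbp, a cold-induced RNA-binding protein, fell in TPN and rose in starvation against sham (log2 fold changes -1.05 and 1.42), and TPN against starvation gave -2.47 (quasi-likelihood adjusted p = 7.2e-04). Hoga1, of hydroxyproline breakdown, overlaps another gene and was at -2.25 and 2.12, with -4.37 between the treatments (adjusted p = 0.00355). Acsm5, an acyl-CoA synthetase that also overlaps another gene, was at -1.82 and 1.09, with -2.91 (adjusted p = 8.3e-04). Tnfrsf23, a decoy receptor, was at 1.33 and -1.07, with 2.40 (adjusted p = 0.00200). Mmp13, a collagenase, was at 1.26 and -0.99, with 2.25 (adjusted p = 0.00130). The list of peptide digestion and amino acid transport was at -0.64 and 0.51 in mean log2 fold change, with -1.15 between the treatments (camera adjusted p = 2.6e-11, adjusted p = 0.436 with an estimated correlation), and its rise in starvation was lost without starvation replicate 3 (mean 0.22). For the 5 genes the contrast of TPN with starvation passed with any 1 library left out. Their calls against sham held less well: in starvation, Hoga1, Acsm5 and Tnfrsf23 lost theirs in 7 of the 9 fits, Mmp13 in 8 and Cirbp in 1 (without sham replicate 3). In TPN, Hoga1 lost its call in 7 fits, Tnfrsf23 in 3 (without any 1 of the TPN libraries), Cirbp in 2 (without TPN replicate 1 or 3) and Mmp13 in 1 (without TPN replicate 1).

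Paneth cell markers were lower in every starvation library (1.70 to 3.03 mean log2 CPM) than in every sham library (4.25 to 4.35). A smaller share of crypts would lower stem cell and cell cycle markers too. Without sham replicate 2 and starvation replicate 3 their mean log2 fold changes were -0.07 and -0.38, against -1.43 for Paneth. Paneth minus stem cell was -1.37 (95% bootstrap interval -1.89 to -0.91, over genes, not pieces). Crypt share alone is thus unlikely. Starvation replicate 3 alone does not carry the fall, since without it the mean was -1.49 (fry adjusted p = 0.00333) against -1.75 with it. Camera adjusted p over all alternatives ran from 5.3e-14 to 0.436. Read sharing between defensins is argued against by the 6 other markers, whose median was -1.08 with all 6 below 0 and 2 past the threshold. A response to starvation, in transcript level or in Paneth cell number, stays a hypothesis.

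Smooth muscle and fibroblast markers were lower in both treatments against sham. For smooth muscle the muscle-rich sham replicate 2 is a likely source of most of the fall, since at most 28.0% of the mean log2 fold change remained without it (-0.66 of -2.36 in TPN and -0.32 of -2.03 in starvation). Camera still called what remained in TPN (adjusted p = 0.00360, range over its alternatives 8.4e-07 to 0.791). Fry did not (adjusted p = 0.446 in TPN and 0.696 in starvation), no member passed over all genes, and the lower of the other sham libraries lay 0.192 below the highest TPN or starvation library in mean log2 CPM. Whether that library is the whole source stays open. For fibroblast markers that library is argued against as the whole source, since the lower of the other sham libraries lay 0.330 above the highest of the 6 TPN and starvation libraries in mean log2 CPM. Without it the mean log2 fold changes were -0.75 of -1.24 in TPN and -0.65 of -1.14 in starvation, with 4 and 1 members past the threshold and Col3a1 still lower in TPN (-2.14, quasi-likelihood adjusted p = 0.00307) and in starvation (-1.68, adjusted p = 0.0255). Over the alternatives its adjusted p ran from 5.1e-11 to 0.0345 in TPN and from 2.9e-07 to 0.0998 in starvation. In starvation part of the fall comes with starvation replicate 3, as the mean was -0.42 without both libraries. Fry did not call the fibroblast list with all libraries (adjusted p = 0.118 in TPN and 0.0962 in starvation) or without sham replicate 2 (0.149 in both). Other differences in the share of stroma between pieces were not tested, and with a response to treatment they stay open.

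Pancreatic acinar transcripts were high in 4 libraries. Prss2 ran from 63.0 to 3468 CPM in those 4 and reached at most 0.160 CPM in the other 5, and Ctrb1 ran from 100.3 to 5160 CPM and reached at most 0.561. Pancreatic tissue carried with the piece, or its reads from another library, would keep the acinar genes in 1 ratio, and the lowest correlation of log2 CPM between the 4 libraries over 16 acinar genes was 0.956. The 4 libraries come from all 3 groups, and no biological explanation was tested. Zg16, which goblet cells also express, was left out; with it the lowest correlation was 0.847, below the 0.9 set for this source and above the 0.8 set against it, so the test would then have been undecided.

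For each pair of groups the real split of 6 libraries is 1 of 10, too few for a share under 0.05. TPN against sham called 1261 genes, starvation against sham 541 and TPN against starvation 857, and 1 of the 10 splits, the real one, reached that number in each, the highest other split giving 0. Camera lists did not stand apart in this way: 6 of 10 splits called as many lists as the real 13 in TPN against sham (highest other 17), 6 of 10 as many as the real 16 in starvation against sham (highest other 22) and 3 of 10 as many as the real 20 in TPN against starvation (highest other 22). By fry, 1 of 10 splits reached the real 6, 4 and 10 lists, the highest others being 1, 0 and 0. Of 100 splits of the 9 libraries, only the real one reached 1586 genes differing among groups (highest other 741). Only it reached 215 shared (highest other 23). Chance is unlikely, but the sham libraries may be a source.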

How the results depend on the processing

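Of the alternatives, only the fit without sham replicate 2 and starvation replicate 3 was chosen after seeing the data. Counts are genes higher and lower in TPN against sham, starvation against sham and TPN against starvation. Reported were 510 and 751, 374 and 167, and 285 and 572. DESeq2 gave 969 and 1339, 931 and 607, and 658 and 1044, with 3316 genes that differ among the groups and 592 shared, in place of 1586 and 215. Fits of only the groups compared gave 1130 and 1644, 2 and 0, and 250 and 295, with 2 shared. Nearly all starvation calls thus rested on a spread estimated with the TPN libraries. Fewer degrees of freedom alone do not explain their loss, as TPN against sham rose. The smooth muscle covariate gave 167 and 343, 118 and 85, and 460 and 788, with 70 shared. A 2-fold minimum gave 282 and 380, 257 and 103, and 169 and 363, with 110 shared. An adjusted p under 0.01 gave 97 and 161, 21 and 9, and 42 and 102, with 268 and 18. Without both libraries the counts were 2232 and 2193, 1612 and 1337, and 1500 and 1705, with 5762 and 1610; of the reported calls 1261 of 1261, 539 of 541 and 857 of 857 remained. With library totals only, 97 genes were lower in starvation. Causes were not tested. Limma voom, RLE and upper quartile factors and both filters kept every count within 1.5 times.

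Leaving out each library in turn gave 83 to 1477 genes higher and 125 to 1705 lower in TPN against sham, 22 to 945 and 10 to 794 in starvation against sham, 43 to 482 and 81 to 826 in TPN against starvation, 286 to 3576 that differ among the groups and 20 to 931 shared, each fit having 1 library fewer. The highest values, apart from 826, came without starvation replicate 3. Lists called ranged from 11 to 17, 14 to 19 and 17 to 22.

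The replicate number as a block gave 203 and 353, 48 and 23, and 133 and 253, with 600 and 38. The numbers do not pair the samples: 2 of 9 same-number pairs had a correlation of deviations over 0.1 (range -0.30 to 0.38, median -0.06), and 1 of 9 libraries correlated best with its own number.

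With an estimated correlation 0, 0 and 0 lists were called in the 3 comparisons by camera in place of 13, 16 and 20, and by fry 6, 4 and 10; other settings called 13 to 18, 16 to 20 and 18 to 21. Of the called lists, smooth muscle alone turned its camera direction, with means near 0 (-0.000728 in TPN and 0.00973 in starvation) and no call under its own covariate, as the construction of that fit requires; its call was also lost with the estimated correlation, by fry and, in starvation, without sham replicate 2. Without sham replicate 2 and starvation replicate 3, 12 list calls were lost: inflammatory genes in TPN against sham; peptide transport, clock, myeloid, neuron and endothelial lists in starvation against sham; and lipid absorption, clock, stem cell, inflammatory, neuron and endothelial lists in TPN against starvation. No named gene that passed changed sign under any alternative run for it. Of the named genes that passed, 62 of 62, 2 of 43 and 59 of 73 kept their call in fits of only the groups compared, 48 of 62, 20 of 43 and 51 of 73 with the replicate block, and 52 of 62, 32 of 43 and 66 of 73 with library totals only. With 1 read worth up to 0.129 CPM, ratios such as those of Cxcl1 and S100a8 have wide counting intervals.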

Other observations

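The tests of aryl hydrocarbon receptor targets below were chosen after 1 of those targets had been seen; the test of Rbm3 was written down before its value was seen. Some lists that passed camera in no comparison held genes that changed, named here after their values were seen. In TPN against sham, fatty acid oxidation and ketogenesis had 7 higher and 2 lower of 36 tested members, and 7 and 8 adjusted over the list alone (camera adjusted p = 0.854). The thioesterases Acot1 (2.6 ± 0.39) and Acot2 (1.18 ± 0.29) and the pantetheinase Vnn1 (1.59 ± 0.35) rose. In bile acid sensing and transport, the ileal bile acid transporter Slc10a2 (2.09 ± 0.48) and the bile acid receptor Nr1h4 (1.09 ± 0.23) rose in TPN and the exporter Abcc3 (-1.60 ± 0.21) fell. That list had 3 higher and 2 lower of 11 tested members, and 3 and 3 adjusted over the list alone (camera adjusted p = 0.791). Of retinoid genes, Aldh1a1 (-1.15 ± 0.15) fell in TPN and Dhrs9 (2.41 ± 0.53) rose, in a list with 2 higher and 1 lower of 11 tested members, and 3 and 4 adjusted over the list alone (camera adjusted p = 0.854). Insr, the insulin receptor, and Bcl6 rose in TPN (1.00 ± 0.16 and 1.82 ± 0.18) and in starvation (0.70 ± 0.16 and 1.27 ± 0.18), in a FOXO and insulin list at 0.14, 0.11 and 0.02 in TPN against sham, starvation against sham and TPN against starvation, with 3 and 0, 3 and 0, and 1 and 1 members higher and lower. With single libraries left out, the TPN calls of Acot1, Abcc3, Aldh1a1 and Bcl6 held in all 9 fits, while those of Acot2, Slc10a2, Vnn1 and Dhrs9 were lost in 7, 6, 5 and 5. The starvation call of Insr was lost in 7.

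In the same order of comparisons, the p53 and apoptosis list was at 0.02, -0.05 and 0.07 with 2 and 2, 1 and 1, and 1 and 2 members higher and lower. Glud1, glutamate dehydrogenase, rose in TPN (0.99 ± 0.20) and in starvation (1.55 ± 0.20), in a glutamine, arginine and urea cycle list at -0.05, 0.08 and -0.13 with 1 and 4, 1 and 0, and 0 and 3. Cybrd1, a ferric reductase, fell in TPN (-2.58 ± 0.44), in an iron and mineral list at -0.33, 0.11 and -0.43 with 2 and 2, 2 and 1, and 0 and 1. Trib3, an ATF4 target, was at -1.55 ± 0.39, 0.45 ± 0.38 and -2.0 ± 0.40, in an amino acid response list at -0.16, 0.14 and -0.30 with 0 and 2, 0 and 0, and 0 and 2. With single libraries left out, the call of Trib3 in TPN against sham was lost in 7 of the 9 fits, and that of Glud1 in TPN in 5. Immediate early genes were at -0.42, -0.08 and -0.34 with 0 and 3, 0 and 1, and 0 and 0. B and plasma cell markers were at 1.85, 3.15 and -1.30 with 0 and 0, 1 and 0, and 0 and 0, and MHC class II genes at -0.03, 0.83 and -0.86 with none. Pancreatic acinar genes were at 2.29, -0.48 and 2.78 with none. The remaining lists were tuft cell markers (0.26, 0.21 and 0.05, with 2 and 0, 0 and 0, and 0 and 0), goblet cell markers (0.34, 0.07 and 0.27, with none), T cell and intraepithelial lymphocyte markers (0.11, 0.37 and -0.27, with none), autophagy and lysosome (-0.01, 0.01 and -0.02, with 1 and 0, 1 and 0, and 1 and 1), tight junction and adhesion (-0.05, -0.02 and -0.03, with 0 and 1, 0 and 0, and 1 and 0), adipocyte markers (-1.71, -0.58 and -1.13, with 0 and 1, 0 and 0, and 0 and 1) and villus tip markers (-0.68, 0.21 and -0.89, with none).

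Single libraries moved the means of these lists. Without starvation replicate 3, villus tip markers were at -0.64, -0.74 and 0.09, tight junction genes at -0.02, -0.35 and 0.33 and adipocyte markers at -1.68, -1.66 and -0.02. The villus tip mean then passed camera in both comparisons against sham, and the tight junction mean in starvation against sham and in TPN against starvation. Without that library, B and plasma cell markers passed in starvation against sham (3.62) and in TPN against starvation (-1.74), as did MHC class II (-1.14), goblet cell (0.44) and amino acid response genes (-0.27) in TPN against starvation. Without starvation replicate 1, villus tip markers passed in TPN against starvation (-1.23) and fatty acid oxidation in starvation against sham (0.36). Without TPN replicate 2, amino acid response genes passed in TPN against starvation (-0.57). Without sham replicate 3, adipocyte markers were at -0.25, 0.88 and -1.13. Pancreatic acinar means ran from -2.43 to 11.6, -8.98 to 8.84 and -1.94 to 11.3, and without TPN replicate 3 passed in TPN against sham (2.84) and against starvation (3.33). The other means of these lists that changed sign with 1 library left out lay between -0.41 and 0.41 in those fits.

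Heat shock genes were lower and Cirbp higher in starvation, and a candidate explanation is a lower body temperature of the starved mice. That hypothesis requires Rbm3, the other well known cold-induced RNA-binding protein, to be higher in starvation than in both other groups. Rbm3 was at 66.9 ± 8.02 CPM in starvation, 38.1 ± 4.34 in sham and 26.8 ± 1.35 in TPN, with a log2 fold change of 0.81 against sham (quasi-likelihood adjusted p = 0.0244) and of -1.32 in TPN against starvation (adjusted p = 0.00204). The contrast with TPN passed with any 1 library left out, but the call against sham was lost in 5 of the 9 such fits (without sham replicate 3, starvation replicate 2 or any of the TPN libraries). It was also lost with library totals only (adjusted p = 0.0790), in the fit of only the groups compared (0.129), with the replicate block (0.0593) and with the smooth muscle covariate (0.0581), and passed in 11 of 20 alternatives (range 1.1e-04 to 0.129). The values are consistent with the hypothesis only to that extent. Body temperature is not among the data, and other regulators stay open.

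Cyp1a1 was lower in both treatments, perhaps from less ligand for the aryl hydrocarbon receptor in the unfed gut. Other receptor targets should then be lower in TPN. Of Cyp1b1, Ahrr, Tiparp and Nqo1, only Nqo1 passed, at -2.63, and it also answers to NRF2. Ahrr was at -1.10, Tiparp at -0.13 and Cyp1b1 at 0.87 (quasi-likelihood adjusted p = 0.0945, 0.623 and 0.432). These values leave the hypothesis open. An unfed gut alone does not explain Cyp1a1 being lower in TPN than in starvation.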
